A study of Mus musculus with 3 samples.

How the data were processed

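Total RNA of kidney from female mice was labelled with biotin from 250 ng per array and hybridised to Affymetrix Mouse Gene 1.0 ST arrays, per the labels' protocols. There were 3 arrays, with 1 for control, 1 for NTS and 1 for NTS with PGE2, and the groups were taken from the labels. The deposited values are on a log2 scale and were made by the authors with Affymetrix Expression Console and its RMA method, per the submitters' processing notes; versions and the genome build are not given in the sources used here. RMA corrects the background, makes the arrays' probe distributions equal and summarises the probes of a set by median polish. Of the 35556 probe sets, 25.4% had exactly equal values on all 3 arrays. In simulated sets with probe noise and no difference, median polish over 3 arrays gave equal values in 79.1%. In simulated sets of 25 probes with probe noise, a true difference of 0.50 on 1 array was estimated as 0.30 on average and one of 2 as 1.83. At a simulated probe SD of 0.40, all 3 values were equal in 29.1% of sets at a true difference of 0.25. This fell to 0.85% at 0.50 and 0% at 1. An exactly equal value therefore does not show that a gene was unchanged, and small differences may be understated. No scanner values were analysed here, so probes could not be set against their background. Differences of named genes whose lower value lay below the 25th percentile of its array may be set against background. Among those with values in the text these were Saa1, Saa2, Sprr2f, Cyp2d12, Ucp1, Adipoq, Cidea and Retnla, and Ptger2 and Eif2s3y lay below it on all 3 arrays.

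Of the 35556 probe sets, 21789 had 1 gene symbol in the platform annotation, 1621 had several and 12146 were unnamed here. Symbols were updated through the gene identifiers of a table of the GRCm38.p6 assembly, which matched 21698 of the single-gene probe sets and altered 0 symbols; no coordinates were used. Probe sets with several symbols or none entered no comparison. Probe sets of one gene were averaged, giving 19938 genes, 999 of them with more than 1 probe set. For genes with 2 bright probe sets, the SD of one probe set's difference was taken from the gap between the 2. On the log2 scale it was 0.22 for NTS against control, 0.22 for NTS/PGE2 against NTS and 0.13 for NTS/PGE2 against control. It was larger in the comparisons with the NTS array, so it may hold real differences between probe sets besides technical spread. It leaves out the spread between animals.

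There were 3 comparisons. A gene entered one if the higher of its 2 values reached the median of all probe sets on that array, and counted as different at a log2 difference of at least 1, which is 2-fold. No test was run. Before the data were examined, 43 gene lists for kidney cell types, inflammation, prostaglandins, stress, metabolism and other tissues, the size rule, the rule for named genes and the alternatives were fixed; some genes stand in more than 1 list. For each list with at least 5 measured members the median difference was set against 10000 random lists of the same size, matched on the mean log2 value over the 3 arrays in 20 bins. The percentile describes these arrays and is not a p-value. It is also no measure of size, since many genes had exactly equal values on both arrays. These made up 37.0% of genes for NTS against control and 41.8% for NTS/PGE2 against control. A small median can therefore lie outside the random range. Macrophage genes, with -0.05 for NTS against control, lay at percentile 0.56. Loop and distal tubule genes, with 0.04 for NTS/PGE2 against control, lay at percentile 99.1. Lists outside the 2.5th to 97.5th percentile numbered 9 above and 12 below of 41 for NTS against control, 7 and 11 for NTS/PGE2 against NTS, and 5 and 14 for NTS/PGE2 against control. Medians and 2-fold counts of lists took all measured members, whether or not they passed the filter. The erythrocyte list, with 3 measured members, got values alone: Alas2 read 10.02 on the control array, 7.27 on the NTS array and 9.07 on the NTS/PGE2 array.

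Named genes were the 10 largest differences each way for the first and second comparison and the 5 largest each way for the third among genes passing the filter, up to 4 members with the largest difference for each list described, and a fixed set of kidney injury, podocyte and PGE2 genes, of which 1 is not reported here. Predicted transcripts, olfactory and vomeronasal receptors and small RNA genes were passed over; these numbered 1 higher and 0 lower for NTS against control, 1 higher and 1 lower for NTS/PGE2 against NTS, and 2 higher and 0 lower for NTS/PGE2 against control.

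The calculation was tested on simulated data for NTS against control over 19938 genes: at a true log2 change of 1.5 up and down, 100.0% and 98.0% of the changed genes passed the size rule, and 4.50% of 200 lists of unchanged genes lay outside the random range. With 8 of 20 members changed by 1.5, 80.0% of 50 lists lay above it. The simulated genes varied independently, while members of a real list may shift together. Their noise was continuous and gave no exactly equal values, while 37.0% of the real genes were equal in this comparison. These rates therefore do not show how often real lists fall outside the range without an effect. Alternatives were other fold sizes, filters, normalizations and probe set rules, lists without their dim members, means in place of medians and other random lists; lists of brown fat, urothelium and sex-biased kidney genes were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used, with R 4.3.3 and limma 3.58.1 for cyclic loess and quantile normalization.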

Results

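Gene expression was measured in the kidney of female mice of 8 to 10 weeks with Affymetrix Mouse Gene 1.0 ST arrays, which read transcripts through probes spread over their exons. One array came from kidney of non-treated control mice. A second came from a mouse group given nephrotoxic serum (NTS), a sheep antiserum that binds the glomerulus and induces an immune nephritis, at 13.5 ug per g of body weight. The third came from a group given the same serum and then prostaglandin E2 (PGE2), a lipid mediator that acts through 4 receptors, at 5 ug per g each day from day 2. Kidneys of the treated mice were taken on day 7. The labels do not state whether the RNA of an array came from 1 animal or from several. With 1 array per group no difference had a replicate check, so no p-value was computed, and the number of arrays limits the precision of every value. The median log2 value was 7.11 on the control array, 7.11 on the NTS array and 7.14 on the NTS/PGE2 array. Across all probe sets Pearson's r was 0.975 between control and NTS, 0.975 between NTS and NTS/PGE2, and 0.991 between control and NTS/PGE2; probe sets are not independent replicates.

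The first comparison, NTS against control, asked what nephrotoxic serum nephritis did to kidney transcripts at day 7. Markers of injured tubules and genes of the cell cycle stood higher on the NTS array, while transporters and enzymes of the tubule segments and markers of the endothelium stood lower. Complement and acute phase genes went both ways. The tubular injury marker Havcr1 (Kim-1) had a log2 value of 6.77 on the control array and 12.63 on the NTS array, a 58.2-fold difference. Among 11778 genes that passed the filter on dim genes, 318 were at least 2-fold higher on the NTS array and 638 at least 2-fold lower. This is a rule of size and not a test.

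The tubular injury list held 20 measured genes, of which 13 were at least 2-fold higher on the NTS array and 0 at least 2-fold lower. Its median difference was 1.32 on the log2 scale, above every one of 10000 random lists matched on expression. After Havcr1, its largest differences were in Krt20, a keratin, at 4.45, in Timp1, an inhibitor of metalloproteinases, at 3.29, and in Tnfrsf12a, the TWEAK receptor, at 2.36. Lcn2 (NGAL), another injury marker, was already bright on the control array at 11.86 and read 13.85 on the NTS array. All 29 measured genes of the cell cycle list were higher on the NTS array, 20 of them at least 2-fold, with a median of 1.47, again above every random list. The mitotic cyclin Ccnb2 differed by 2.79, the kinase Cdk1 by 2.68, cyclin A2 (Ccna2) by 2.56 and the proliferation marker Mki67 by 2.37.

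The complement and acute phase list had a median of 0.34 over 21 genes, with 13 higher and 7 lower on the NTS array, 7 and 3 of them at least 2-fold. The fibrinogen chains Fgb and Fgg differed by 4.43 and 4.10, and the serum amyloid genes Saa2 and Saa1 by 4.15 and 3.94. Saa2 and Saa1 read 5.36 and 3.73 on the control array, below its 25th percentile of 5.77, so these differences are taken from values that may be background. The 2 genes are also close in sequence, so their separate values are uncertain. The genes at least 2-fold lower, named after their values were seen, were the complement inhibitor gene Serping1 at -1.74, the acute phase gene Orm1 at -1.71 and the complement receptor gene C3ar1 at -1.33. Fgb also belonged to the list of liver genes, whose median over 9 genes was -0.33, with a mean of 0.02, and whose albumin gene Alb was lower on the NTS array by a log2 difference of -2.29. Outside the lists, the 10 largest positive differences included Sprr2f, an epithelial cornified envelope gene of a family of close copies, at 3.73, the protease inhibitor Serpina3n at 3.62 and the glycoprotein gene Lrg1 at 3.46. The list of p53 targets had a median of 0.54 over 16 genes, with Sesn2 at 1.58 and Trp53inp1 at 1.05. The renal progenitor and development list had a median of 0.44 over 13 genes, with Foxm1 at 1.85, Cd44 at 1.35 and Sox9 at 1.30. Immediate early genes had a median of 0.25 over 19 genes, in which Klf6 was higher by 1.70 and Nr4a1 lower at -1.22.

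Of 27 proximal tubule genes, 16 were at least 2-fold lower on the NTS array and 0 at least 2-fold higher, with a median of -1.23, below every random list. Gatm, the first enzyme of creatine synthesis, differed by -2.93, the phosphate transporter Slc34a3 by -2.81, the organic anion transporter Slc22a8 by -2.31 and Cyp2e1 by -2.20. The loop and distal tubule list had a median of -1.12 over 15 genes, with Egf at -3.10, Pvalb at -2.60 and the potassium channel Kcnj1 at -1.94. The collecting duct list had a median of -0.76 over 17 genes, with the water channels Aqp4 at -2.62 and Aqp2 at -1.74 and the anion exchanger Slc4a1 at -1.85. The endothelium list had a median of -0.96 over 20 genes, none of them higher on the NTS array, with the angiopoietin receptor Tek at -2.26, Eng at -2.01, Emcn at -1.84 and Plvap at -1.76. The medians of these 3 lists lay below every random list as well. Among the largest negative differences of single genes were Cyp2d12 at -4.53, Cyp2d26 at -4.36, Akr1c14 at -4.19, the tyrosine catabolism enzyme Hpd at -4.07 and Dnase1 at -3.98; the Cyp2d and Akr1c families hold near copies, so these values may mix family members.

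The podocyte list, of the cell that forms the glomerular filter, had a median of 0.02 and a mean of -0.04 over 20 genes, and the median lay at percentile 88.1 of random lists. The slit diaphragm gene Nphs1 read 7.36 on the control array and 7.38 on the NTS array, and the podocyte transcription factor Wt1 read 8.30 and 8.74; Tcf21 was the exception at -1.88. The matrix and myofibroblast list went both ways, with a median of 0.06 and a mean of -0.03 over 26 genes: the collagen gene Col1a1 was higher by 2.06 and fibronectin (Fn1) by 1.53, while decorin (Dcn) was lower at -2.55 and Postn at -1.35. The macrophage list went both ways too, with a median of -0.05 over 27 genes, in which Cd68 was higher by 2.23, Cd14 by 2.15 and Plac8 by 1.89, and Ly86 was lower at -1.35. Lists of alternatively activated macrophages (15 genes), neutrophils (16), T and NK cells (24), B and plasma cells (15), chemokines and adhesion molecules (21) and cytokines and inflammasome genes (22) each had a median of 0, with many exactly equal values; 4, 1, 0, 2, 11 and 7 of their members were bright enough for the filter. The only members of these lists at least 2-fold different were Retnla, Icam1 and Cxcl9. Retnla, of the alternatively activated macrophage list, was lower at -2.52, with an NTS value that may be background. It was about as low on the NTS/PGE2 array, at 4.80 against 4.78 on the NTS array and 7.30 on the control array. Of the chemokines and adhesion molecules, Icam1 was higher by 1.10 and Cxcl9 lower at -1.09. The monocyte chemokine gene Ccl2 read 6.43 on all 3 arrays, below each array's median. Interferon response genes had a median of -0.26 over 21 genes, with Rsad2 at -2.58 and Ifit3 at -2.00.

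In the prostaglandin list, 3 of 21 genes were at least 2-fold lower on the NTS array and 0 at least 2-fold higher, with a median of -0.16. These were Hpgd, which degrades prostaglandins, at -2.33, the cyclooxygenase gene Ptgs2 at -1.23 and the EP3 receptor gene Ptger3 at -1.12. Ptges, the inducible PGE2 synthase, read 9.77 and 9.79, and the EP1 receptor gene Ptger1 read 8.18 and 7.54. The EP2 receptor gene Ptger2 read 5.55 and the EP4 receptor gene Ptger4 7.59 on all 3 arrays; Ptger2 lay below the 25th percentile of each and may be background.

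Genes of fat stood out on the control array. The adipose list, fixed as a check for tissue other than kidney, had a median of -2.86 over 11 genes for NTS against control. The brown fat uncoupling protein gene Ucp1 read 11.84 on the control array, 5.72 on the NTS array and 5.91 on the NTS/PGE2 array, and Retn, Adipoq and Cidea were lower on the NTS array by differences of -4.97, -4.48 and -3.52. Car3 at -5.36 and the lipogenic gene Thrsp at -3.99, also abundant in fat, completed the 10 largest negative differences. Smooth muscle genes had a median of -0.33 over 9 genes, with Cnn1 at -1.77. Lists of adrenal cortex (8 genes), skeletal muscle (10) and pancreas (8) had medians of 0. Without fat, urothelium and smooth muscle markers, an alternative chosen after seeing the data, 318 genes were higher and 615 lower on the NTS array. Only listed markers were left out: Car3 and Thrsp were in none of these lists, so the 615 still held genes abundant in fat.

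**Figure D1:**
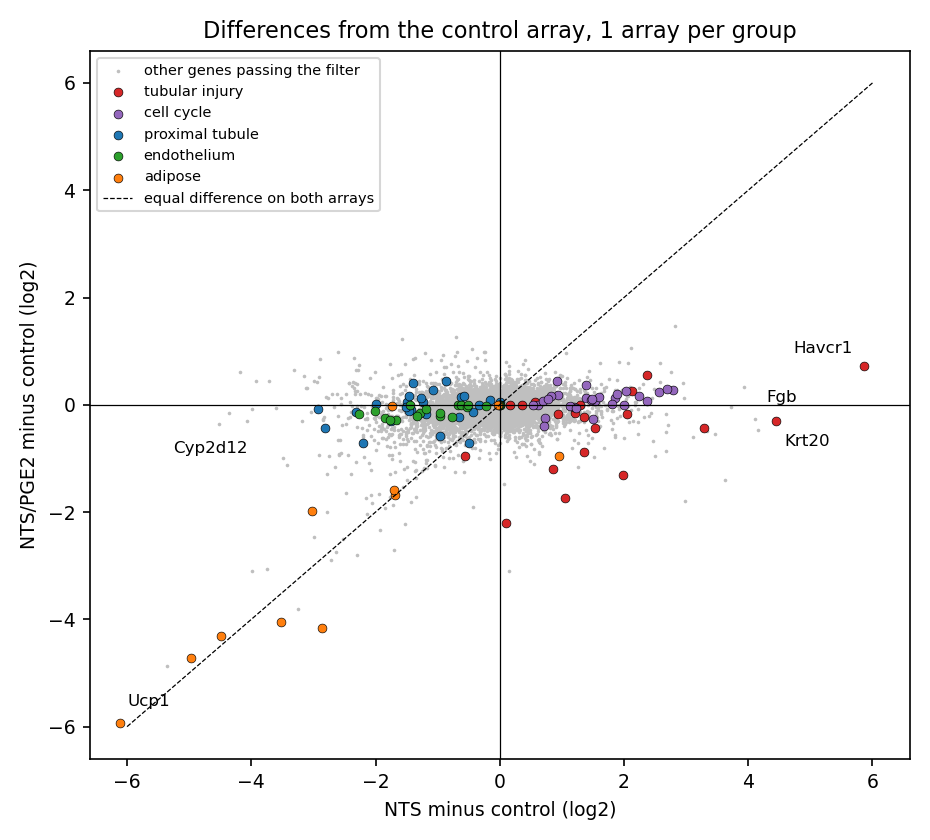
Log2 difference of NTS from control (horizontal axis) against log2 difference of NTS/PGE2 from control (vertical axis); each point is a gene, gray points passed the filter on dim genes, colored points are members of 5 gene lists, and the dashed line marks equal differences. Havcr1 lies at 5.86 and 0.73, near the horizontal axis with the cell cycle, proximal tubule and endothelium genes, while Ucp1 lies at -6.12 and -5.93, near the dashed line.

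The second comparison, NTS/PGE2 against NTS, asked how daily PGE2 after the onset of nephritis altered the kidney's transcripts. The gene groups that were higher on the NTS array than on the control array were lower on the NTS/PGE2 array than on the NTS array, and tubule and endothelium genes were higher. Havcr1 read 7.50 on the NTS/PGE2 array, 35.1-fold below the NTS array, and Akr1c14, a hydroxysteroid dehydrogenase, read 11.19, 27.8-fold above it. Of 11699 genes passing the filter, 486 were at least 2-fold higher on the NTS/PGE2 array and 384 at least 2-fold lower.

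All 20 tubular injury genes were lower on the NTS/PGE2 array, 16 of them at least 2-fold, with a median of -1.91. Krt20 differed by -4.75, Timp1 by -3.72 and Lcn2 by -3.29. All 29 cell cycle genes were lower, 21 at least 2-fold, with a median of -1.37, and Ccnb2 differed by -2.52 and Cdk1 by -2.39. The complement and acute phase list had a median of -0.61, with 8 of 21 genes at least 2-fold lower, among them Fgb at -4.69, Saa2 at -4.61, Fgg at -4.36 and Saa1 at -3.61. Cyp27b1, which makes active vitamin D, read 11.98 on the NTS array and 7.20 on the NTS/PGE2 array, against 8.995 on the control array. Serpina3n at -5.01, Lrg1 at -4.01 and Sprr2f at -3.77 were among the 10 largest negative differences. Immediate early genes had a median of -0.78, with Klf6 at -1.71, Zfp36 at -1.55 and Egr1 at -1.47, and p53 targets a median of -0.42. MHC class II genes, which present antigen, had a median of -0.37 over 6 genes, with H2-DMa at -1.29 and H2-Ab1 at -1.01. In the macrophage list, with a median of -0.09, Cd68 was lower at -2.77 and Cd14 at -2.45, while Csf1r, the receptor for the macrophage growth factor CSF1, was higher by 1.25.

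Of 27 proximal tubule genes, 17 were at least 2-fold higher on the NTS/PGE2 array and 0 at least 2-fold lower, with a median of 1.34, above every random list. Gatm differed by 2.84, Slc34a3 by 2.38, Slc22a8 by 2.18 and Miox by 2.00. Loop and distal tubule genes had a median of 0.90, with Egf at 3.41, collecting duct genes a median of 0.57, with Aqp4 at 2.82 and Aqp2 at 2.23, and endothelium genes a median of 0.79, with Tek at 2.09 and Eng at 1.89. The 10 largest positive differences of single genes also held Cyp2d26 at 4.202, Tmem207 at 4.16, Cyp2d12 at 4.16, the organic anion transporters Slc22a7 at 3.96 and Slc22a19 at 3.67, Dnase1 at 3.90, Hpd at 3.76, the meprin subunit gene Mep1b at 3.76 and the bile acid transporter Slc10a2 at 3.59. The podocyte list had a median of 0, with Tcf21 at 1.77 and Npnt at 1.09. The prostaglandin list had a median of 0.12, with Hpgd higher by 2.58, Ptger3 by 1.29 and Ptgs2 by 0.96. The renin and angiotensin list had a median of 0.33 over 9 genes, with the converting enzyme gene Ace at 1.60 and Mme at 1.07. Adipose genes had a median of 0.12, at percentile 96.3 of random lists, and a mean of -0.02, but the 4 of 11 members passing the filter went both ways, with Lpl higher by 1.72 and Fabp4 by 1.04 and Plin4 lower at -1.92 and Cidec at -1.31.

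**Figure D2:**
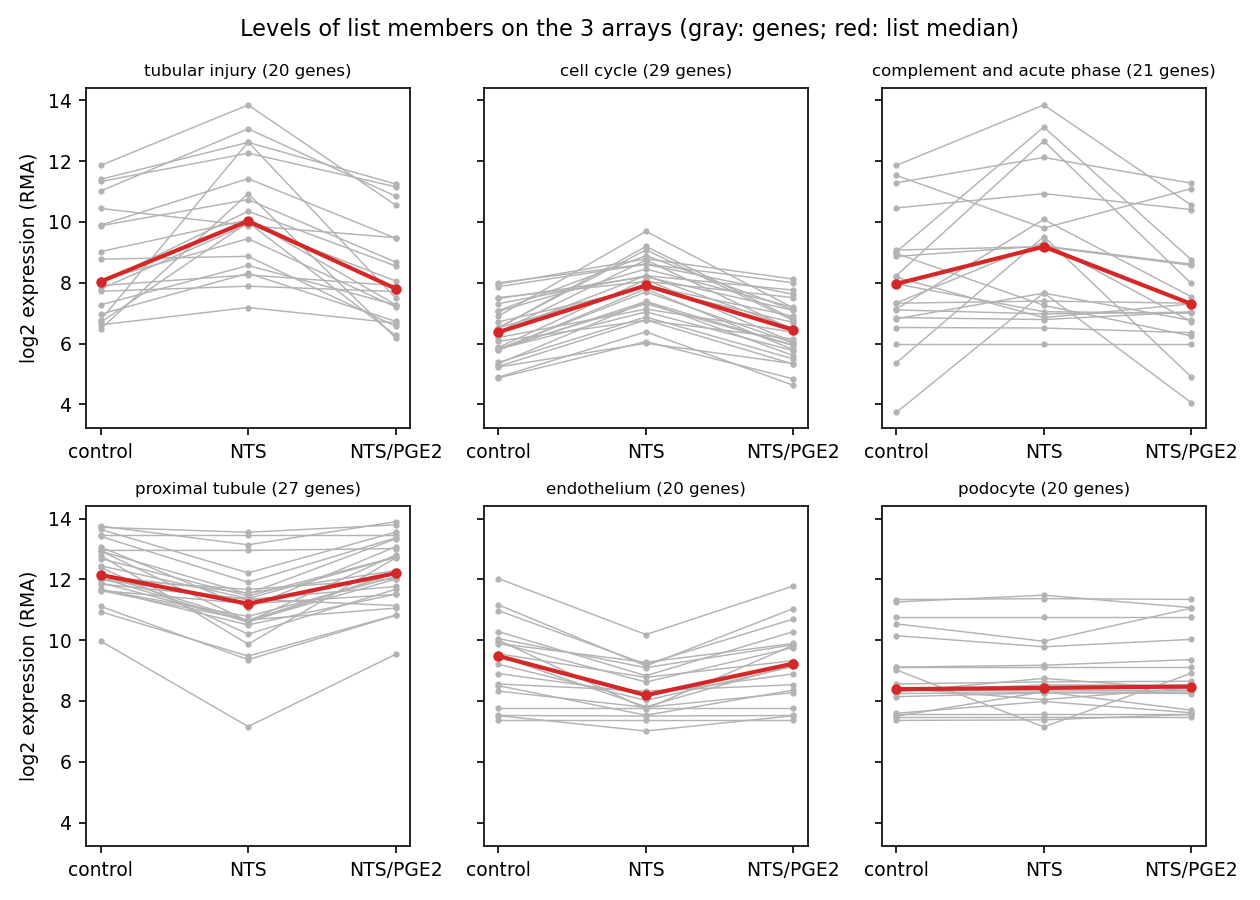
Log2 expression (vertical axis) of the members of 6 gene lists on the control, NTS and NTS/PGE2 arrays (horizontal axis); gray lines are single genes and the red line is the list median, with 1 array per group and no error bars. The tubular injury and cell cycle lists peak on the NTS array, the proximal tubule and endothelium lists have their lowest median there, and the median of the podocyte genes' own differences between NTS and control, which is not the step of the red line, is 0.02.

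The third comparison, NTS/PGE2 against control, asked what still set the treated kidney apart from the control kidney. Few genes did. Of 11534 genes passing the filter, 7 were at least 2-fold higher on the NTS/PGE2 array and 76 at least 2-fold lower, and the largest negative differences were genes of fat: Ucp1 at -5.93, Car3 at -4.86, Retn at -4.72, Adipoq at -4.30 and the lipid droplet gene Cidec at -4.17. Without the listed fat, urothelium and smooth muscle markers 7 and 55 genes were left. Car3 was in none of these lists, so the 55 still held it. The higher genes named by the rule were the organic anion transporter family member Slc22a26 at 1.25, Rnf24 at 1.23, the mucin gene Muc19 at 1.17, Hmox1 at 1.05 and the amino acid transporter Slc6a15 at 1.04. Hmox1, the inducible heme oxygenase, read 8.62 on the control array, 10.73 on the NTS array and 9.67 on the NTS/PGE2 array.

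The proximal tubule median was 0 against control, and none of its 27 genes differed 2-fold. Medians against control were 0.04 for loop and distal tubule genes, -0.11 for collecting duct genes, -0.10 for endothelium genes and 0.11 for cell cycle genes, with 0 genes at least 2-fold different in each of these lists. Only 8 of the 29 cell cycle genes passed the filter in this comparison, so most of them were dim on both arrays. The tubular injury list had a median of -0.20 against control, with 4 of 20 genes at least 2-fold lower: Krt19 at -2.21, S100a6 at -1.75, Lcn2 at -1.30 and Krt18 at -1.19. Urothelium genes, in a list written after some values were seen that also holds Krt19, had a median of -1.16 against control, with 8 of 14 at least 2-fold lower. Havcr1 stayed above control by 0.73, a 1.66-fold difference. Macrophage genes had a median of -0.30 and 21 of 27 were lower than on the control array, with Lyz2 at -1.03. Medians were also negative for complement and acute phase genes at -0.25, with Orm1 at -2.71, for immediate early genes at -0.27, with Egr1 at -1.91, for MHC class II genes at -0.32 and for interferon response genes at -0.21. ER stress genes had a small positive median of 0.09 over 16 genes, with the chaperone gene Hspa5 at 0.48. The adipose median was -1.98 and the smooth muscle median -0.38.

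**Figure D3:**
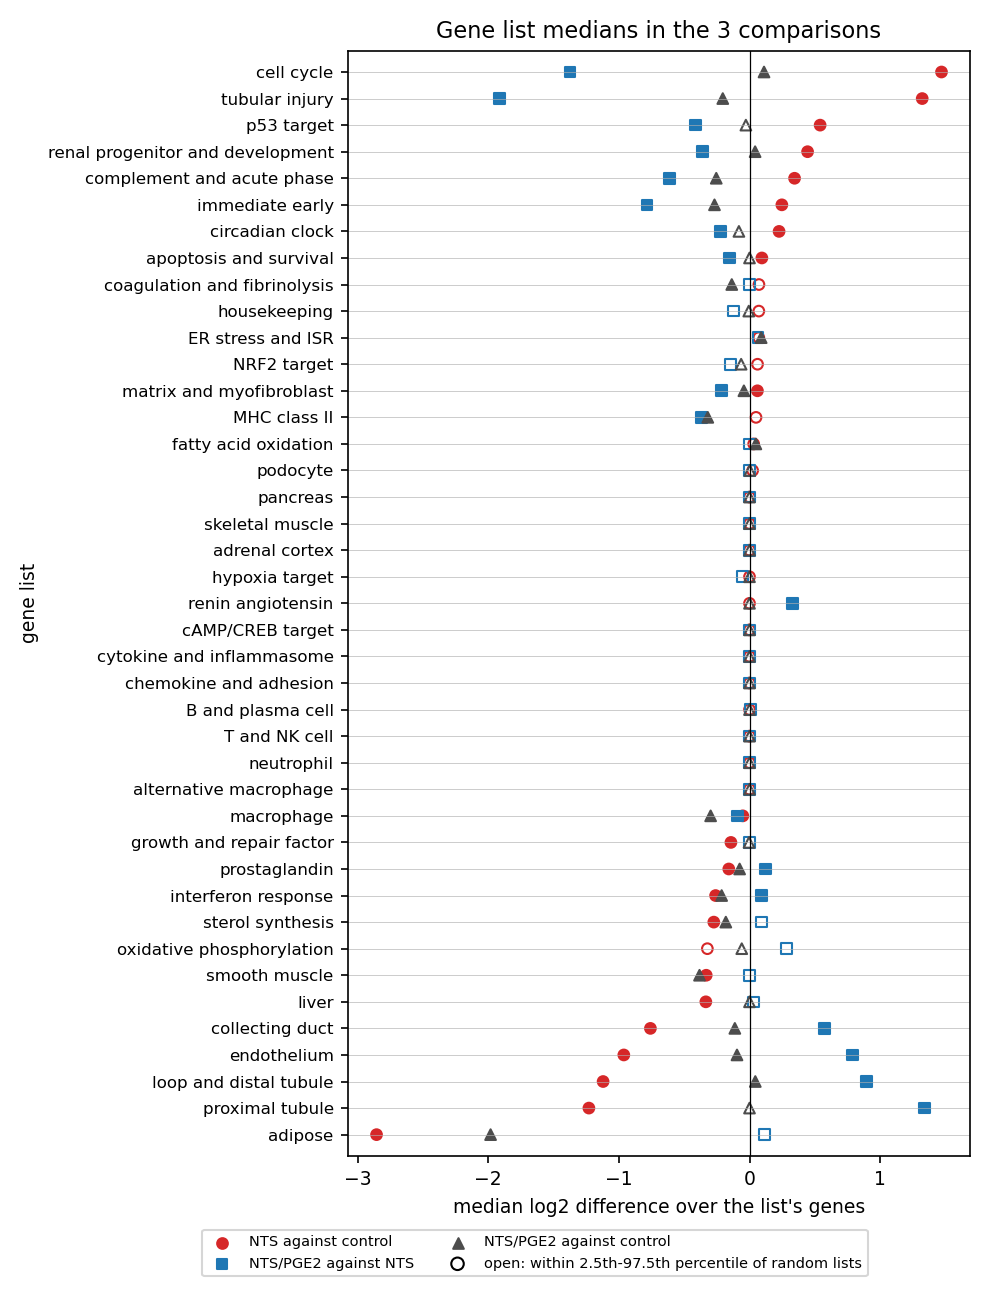
Median log2 difference of each gene list (horizontal axis) for 41 lists (vertical axis) in the 3 comparisons; filled symbols lie outside the 2.5th to 97.5th percentile of 10000 random lists matched on expression, open symbols inside it. A filled symbol can mark a small median, such as 0.04 for loop and distal tubule genes for NTS/PGE2 against control. The cell cycle median is 1.47 for NTS against control, -1.37 for NTS/PGE2 against NTS and 0.11 for NTS/PGE2 against control, while the adipose median is -2.86, 0.12 and -1.98.

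Set side by side, the genes that differed on the NTS array lay near the control level on the NTS/PGE2 array. Of the 318 genes at least 2-fold higher on the NTS array, 317 lay nearer to control on the NTS/PGE2 array and 281 lay within 0.5 log2 units of it. Of the 638 at least 2-fold lower, 620 lay nearer and 472 within 0.5. The median difference from control went from 1.35 on the NTS array to -0.001 on the NTS/PGE2 array for the first set, and from -1.40 to -0.21 for the second. These shares depend on the array the genes were chosen on: 98.0% of these 956 genes lay nearer, with 0.09 of the difference left, but of the 83 genes at least 2-fold different between NTS/PGE2 and control 61.4% did, with 0.73 left. All 29 cell cycle genes, 24 of 27 proximal tubule genes, 18 of 20 endothelium genes and 16 of 20 tubular injury genes lay nearer to control. In the adipose list the ratio of the median difference left to that on the NTS array was 0.69.

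Both of these differences use the NTS array, so that chance values on it alone tie them together. Across 19938 genes, which are not independent replicates, the differences NTS minus control and NTS/PGE2 minus NTS had a Pearson's r of -0.898 and a covariance of -0.198, against -0.50 and -0.0227 simulated for 3 arrays with noise and no effect. The simulated noise was as large as the spread between the control and NTS/PGE2 arrays across genes; how far animals of 1 group differ was not measured, and the simulated covariance depends on it. Of 318 genes higher on the NTS array and 384 lower on the NTS/PGE2 array than on the NTS array, among 11626 genes passing both filters, 274 were shared, where independent lists of these sizes would share 10.5; in the other direction 405 were shared of 597 and 481, against 24.7. The numbers for independent lists leave out the shared NTS array, which could not be split, and part of the excess may come from it.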

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

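Signals above control appeared in probe sets that no comparison used, and signals below control did too. Among probe sets with several gene symbols, 39 were at least 2-fold higher and 62 at least 2-fold lower on the NTS array than on the control array, of 855 passing the filter; on the NTS/PGE2 array 1 was higher and 27 lower, of 847. Among unnamed probe sets whose identifiers follow the first named one, 53 were higher and 57 lower of 1891 on the NTS array, and 6 and 39 of 1837 on the NTS/PGE2 array. Among those whose identifiers precede it, 156 were higher and 100 lower of 2818 on the NTS array, and 23 and 14 of 2784 on the NTS/PGE2 array. What the unnamed probe sets measure is not given in the annotation used, so they may not stand for genes. The genes behind the probe sets with several symbols were not analysed here.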

How the results depend on the processing

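No paired analysis was possible because each group had 1 array. Gene counts moved with the fold size by construction. At 1.5-fold, 898 genes were higher and 1406 lower for NTS against control, 1167 and 1045 for NTS/PGE2 against NTS, and 64 and 248 for NTS/PGE2 against control; at 3-fold these were 112 and 249, 180 and 128, and 0 and 36. For NTS/PGE2 against control, quantile normalization gave 12 higher genes, the cause of which was not tested, and a filter at the 75th percentile 43 lower genes, fewer having entered. The other 46 of 60 gene counts and all 42 counts of lists outside the random range stayed within 1.5 times of the values reported. Of the genes at least 2-fold different on the NTS array, or 1.5-fold under 1 of the 5 other settings, 97.7% to 98.1% lay nearer to control on the NTS/PGE2 array under these settings. Among genes chosen instead on NTS/PGE2 against control, 61.4% did, and the share of the difference left was 0.73 against 0.09, since that choice takes the genes that stayed apart. With means in place of medians, 2 values of fixed lists outside the random range changed sign, for NTS against control matrix and myofibroblast to -0.030 and liver to 0.024, both holding members that went both ways. Of fixed lists inside the range, these did: podocyte for NTS against control to -0.04, adipose to -0.02 and cAMP and CREB targets to -0.05 for NTS/PGE2 against NTS, and NRF2 targets to 0.04 for NTS/PGE2 against control. Of 839 list values, 757 stayed within the 95% bootstrap interval over members. Lists outside the random range under every alternative numbered 15 of 21 for NTS against control, 16 of 18 for NTS/PGE2 against NTS and 11 of 19 for NTS/PGE2 against control. Those lost somewhere for NTS against control were apoptosis and survival, clock, growth and repair, macrophage, matrix and liver. For NTS/PGE2 against NTS they were interferon response and renin and angiotensin. For NTS/PGE2 against control they were cell cycle, coagulation, collecting duct, endothelium, loop and distal tubule, matrix, prostaglandin and sterol synthesis. Of 324 values of named genes, 322 moved by less than the spread between probe sets. Many of them could hardly move. Taking the brightest probe set leaves a gene with 1 probe set as it was, which held for most named genes. Centring on the array medians shifted all genes alike and by little. Signal over background was not analysed here, which limits lists with few members passing the filter, among them T and NK cells and adrenal cortex, each with 0 members passing for NTS against control.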

Other observations

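Small nucleolar and U RNA genes, which guide RNA modification and processing, were not among the lists fixed beforehand. Over 56 of them the median difference was 0.51 for NTS against control, with 15 at least 2-fold higher and 0 at least 2-fold lower, and -0.86 for NTS/PGE2 against NTS; Snord118 read 8.90 on the control array, 12.23 on the NTS array and 8.41 on the NTS/PGE2 array. Clock genes, with a median of 0.23 over 17 genes for NTS against control, went both ways: the activator Arntl was higher by 1.67, and the output genes Hlf and Dbp were lower at -1.78 and -1.504. Sterol synthesis genes had a median of -0.27 over 15 genes, with Cyp51 at -2.43, growth and repair factors -0.14 over 20 genes, with the klotho gene Kl at -1.504, and oxidative phosphorylation genes -0.32 over 24 genes, at percentile 3.77 of random lists. Fatty acid oxidation genes had a median of 0.03 over 23 genes, with Pdk4 higher by 1.91 and Acadm lower at -1.16, and apoptosis and survival genes a median of 0.09 over 21 genes, with Bcl2l1 higher by 0.98. NRF2 targets had a median of 0.06 over 13 genes, coagulation and fibrinolysis genes 0.07 over 12 genes with Anxa2 at 1.53, and housekeeping genes 0.07 over 10 genes; cAMP and CREB targets and hypoxia targets had medians of 0 over 17 and 14 genes.

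Urothelium genes, in a list of 14 written after some values were seen, had a median of -0.97 for NTS against control and -1.16 for NTS/PGE2 against control, with Psca reading 10.09 on the control array, 6.85 on the NTS array and 6.29 on the NTS/PGE2 array. Sex-biased kidney genes were also listed after some values were seen. The 7 female-biased genes had a median of -2.94 for NTS against control and 3.43 for NTS/PGE2 against NTS. The 14 male-biased genes went both ways for NTS against control, with 3 at least 2-fold higher, 4 at least 2-fold lower and a median of -0.17; Cyp4a12b was higher by 3.10 and Cyp4a12a by 2.67. Xist read 12.38, 12.49 and 12.38 on the control, NTS and NTS/PGE2 arrays, and the Y-linked gene Eif2s3y 3.19 on all 3. The longest run of unnamed probe sets with neighbouring identifiers at least 2-fold lower on the NTS array held 9, with a median difference of -5.29 for NTS against control and -3.35 for NTS/PGE2 against control.

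In the 3 patterns weighed next, the tests of fat loss, of brown fat as the source of the lower genes, of a kidney without nephritis and of median polish as the source of equal values were chosen after the results were seen.

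The NTS array stood apart and the NTS/PGE2 array lay near control. A general loss of abundant transcripts on the NTS array would lower ribosomal protein genes. On the normalized scale their median over 59 genes was higher there by 0.25 (95% bootstrap interval 0.11 to 0.41). The interval is over genes and leaves out the spread between arrays and animals. RMA makes the arrays' distributions equal, so a loss shared by all bright transcripts may not show in these values and is not excluded. Brown fat on control kidney tissue would leave most lower genes low on both serum arrays. But of the 638 genes lower on the NTS array, 9.56% were also 2-fold lower on the NTS/PGE2 array. Median polish setting the NTS/PGE2 array equal to control would give equal values, found for 3.14% of 956 genes. This share does not test a pull that stops short of equality, since simulated true differences of 0.50 were estimated as 0.30. An array labelled NTS/PGE2 from a kidney that had little nephritis, or a mouse that responded weakly to the serum, cannot be told apart from recovery, since the tubular injury median lay at -0.20 against control and both predict a value near control. An effect of PGE2 stays among the open explanations, untested without further animals.

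Fat genes on the control array may come from brown fat left on the control kidney tissue. A second set of 16 brown fat genes was written before their values were seen. Their median was higher on the control array than the mean of the other arrays by 0.36. The bootstrap interval over genes, not over animals, was 0.17 to 0.74, and 14 genes were higher. This fell short of the 0.5 set beforehand, and 11 of the 16 were above the array median on the NTS/PGE2 array too. The test therefore decided nothing. Ucp1, at 11.84 against 5.72 and 5.91, had the largest difference in the first list, in which 3 of 11 genes were above that median. Loss of fat in both groups given serum cannot be told apart from a cleaner dissection: the adipose median differed by 0.12 between the serum arrays, over members that went both ways, which decided nothing. Urothelium genes, with medians of -0.97 and -1.16 against control, were lower on the NTS and NTS/PGE2 arrays too. So were smooth muscle genes, with -0.33 and -0.38. Fat loss alone would not give this, but it does not exclude fat loss. The urothelium list was written after some values were seen, so its medians are no separate test. On the NTS array 11 of its 14 genes were lower than on the control array and 2 were higher.

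Equal values on different arrays may come from median polish over 3 arrays. Values were equal on all 3 arrays in 25.4% of probe sets, and noise alone put through median polish gave 79.1% in simulated sets. A floor on low values would put most of them at 1 value, but the most common value held 0.742% of the 9025 probe sets, which took 3344 different values. No biological explanation was tested.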
